A study of Mus musculus with 4 samples.

How the data were processed

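Total RNA of C3H10T1/2 cells was labelled with biotin and hybridised to Affymetrix 3' expression arrays, with 2 control arrays and 2 arrays of cells given 100 ng/ml BMP3 for 6 hours, per the labels' protocols. The deposited table holds 1 log2 value per probe set and array. The log2 scale was inferred from the range and shape of the deposited values and is not stated by the sources used here. Partek is named in the submitters' processing notes, with no version or step. The background correction, the normalization between arrays and the summary of probes to probe sets are not given in the sources used here. If the scale were another log base, each fold here would change with it. A normalization that equalises arrays would also hide a change that moved most transcripts one way.

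Groups and replicate numbers were taken from the sample titles. The labels call the arrays biological replicates and do not say whether a number marks a shared day or batch, so the fit had no term for it. The values were used as deposited, with no filter on dim probe sets, after 64 control probe sets were left out. Of the 45037 probe sets tested, 34945 carried 1 gene symbol in the platform annotation, 932 several, and 9160 were not listed with a gene. Symbols were checked through Entrez identifiers for 34741 probe sets, and 0 changed. A probe set with several symbols named no gene. Each of 18193 genes was represented by the probe set with the highest mean over the 4 arrays. No genome build was used, and no coordinates are given. For 40 list members with no probe set of their own, values are not analysed here.

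Differences were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, 1.18 prior degrees of freedom), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. A looser count took an unadjusted p under 0.05 with a fold of at least 1.5. Confidence intervals are at 95%. Before the data were examined, 33 gene lists of signalling targets, pathways, lineage markers and other cell types were fixed. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, both directional and for either direction.

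The genes named were set by a rule fixed before the data were examined. It took up to 15 genes with the largest differences in each direction past the adjusted threshold, filled to 10 by smallest unadjusted p among genes with a fold of at least 1.5. It added from each list up to 4 members past the threshold or otherwise up to 2 of smallest p, and a fixed set of SMAD targets, receptors and lineage genes. It gave 94 genes. Any other gene is named as chosen after its values were seen.

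The fit was tested on simulated data of 45037 probe sets in the same design. At adjusted p under 0.05 it called 50% of probe sets given a log2 change of 1 and 76% of those given a change of 2, with 11 unchanged probe sets called. Under the looser threshold 96% and 99% were recovered. The fitted change was 0.998 of the true one. Of unshifted lists, 2.5% had an unadjusted camera p under 0.05. The changed probe sets were drawn at random from all probe sets, dim ones included, and only 17152 of the 45037 averaged a log2 value of 6 or more. The shares recovered therefore do not show what share of changed genes at brighter levels the test would find. The noise of each simulated probe set was independent of the others, and the lists were random probe sets. The simulation therefore does not show how often camera calls lists of genes that vary together.

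Alternatives were the replicate number as a block, each array left out, quantile normalization, median centring, cyclic loess, leaving out the dimmer probe sets by rank or under a log2 value of 6, other variance priors, an ordinary linear model, 1 probe set or the mean of all probe sets per gene, an offset of 16 on the linear scale, and other thresholds. The effects of these on lists called by fry in either direction were added after those calls were seen.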

Results

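Gene expression was measured in C3H10T1/2 cells, a mouse mesenchymal stem cell line, that were either left untreated or exposed to 100 ng/ml recombinant human bone morphogenetic protein 3 (BMP3) for 6 hours. BMP3 is a secreted member of the TGF-beta superfamily. Total RNA of 2 control cultures and 2 BMP3 cultures, named as biological replicates by the labels, was hybridised to 4 Affymetrix 3' expression arrays. The deposited values were read as log2 intensities of 45037 probe sets after 64 control probe sets were left out. The arrays had median log2 values of 3.35 and 3.40 (control) and 3.36 and 3.31 (BMP3), and 37.7% to 38.6% of probe sets reached a log2 value of 6. Over probe sets averaging at least that level, Pearson's r between arrays ran from 0.964 to 0.988 across probe sets, which are not independent replicates. Control replicates 1 and 2 gave 0.988 and BMP3 replicates 1 and 2 gave 0.979, while each replicate of 1 group against the other group gave 0.964 to 0.981. Each group value below is a mean of 2 arrays, and this number limits its precision.

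The design addressed which transcripts differ after 6 hours of BMP3. No single probe set passed limma's adjusted p threshold of 0.05 (0 higher, 0 lower, smallest adjusted p = 0.213), so the differences of the genes named below did not pass the test. At an unadjusted p under 0.05, 3779 probe sets were counted (1667 higher, 2112 lower), against 2251.85 for no change. With a fold of at least 1.5 as well, 364 probe sets were higher and 901 lower, which corresponded to 215 and 300 genes. The groups did not overlap at 36.3% of probe sets, and chance gives 33.3% for 2 arrays against 2. Of 33 gene lists fixed before the data were examined, 6 were shifted at a camera adjusted p under 0.05 with a preset inter-gene correlation of 0.01. Cell cycle, cholesterol synthesis, ribosome biogenesis and heat shock genes were shifted higher, and interferon-stimulated and Hedgehog pathway genes lower. With a correlation estimated for each list, none of the 6 calls held (adjusted p = 0.906 for each).

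Among the genes with the smallest unadjusted p and a fold of at least 1.5, those with higher values in BMP3 arrays included Polr3g, a subunit of RNA polymerase III, at 3.99 ± 0.04 in control and 5.47 ± 0.04 in BMP3 arrays (mean log2 ± SD, 2 arrays each). Its log2 difference was 1.48 with a standard error of 0.05 (limma adjusted p = 0.213). Differences from here on are given on the log2 scale as BMP3 minus control ± SE, for the brightest probe set of a gene. Other probe sets of the same gene can differ from it, as with Sox9 (-0.38 to 0.11) and Adamts5 (-1.53 to -0.64). Cks2, a subunit that binds cyclin-dependent kinases, had a difference of 0.98 ± 0.03, the transcription factor gene E2f8 1.38 ± 0.05, and L1cam, which encodes a cell adhesion molecule, 1.19 ± 0.05. Ubtd1 had 1.15 ± 0.04, Serpinb9b 1.54 ± 0.06, Rasa1 0.76 ± 0.03, Osbpl10 0.89 ± 0.05 and the potassium channel gene Kcnn4 0.93 ± 0.06. Msln averaged 2.87 in control arrays, below the median of each array, and 3.93 in BMP3 arrays, so no difference is given. Polr3g, Osbpl10, Msln and Fmo1 stayed under a log2 value of 6 on all arrays. Genes with lower values in BMP3 arrays included Nr3c2, the mineralocorticoid receptor, at 7.17 ± 0.02 in control and 5.95 ± 0.02 in BMP3 arrays (difference -1.21, SE 0.04). Slc1a6, a glutamate transporter, had a difference of -2.23 ± 0.08 and the kinase gene Stk17b of -1.19 ± 0.04. Fmo1 averaged 4.84 in control and 3.02 in BMP3 arrays, the latter below the median of each array, so no difference is given. Clu, which encodes the secreted chaperone clusterin, had -1.12 ± 0.06 and Vcan, which encodes the matrix proteoglycan versican, -0.65 ± 0.03. Ankrd29 (-0.72), Zfyve16 (-0.82), Scpep1 (-0.63) and Eya4 (-0.63) completed the 10 genes of this direction. The adjusted p was 0.213 for each of these 20 genes. Picking genes by smallest p from 2 arrays per group favours small standard deviations and errors, so theirs can understate the spread.

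**Figure D1:**
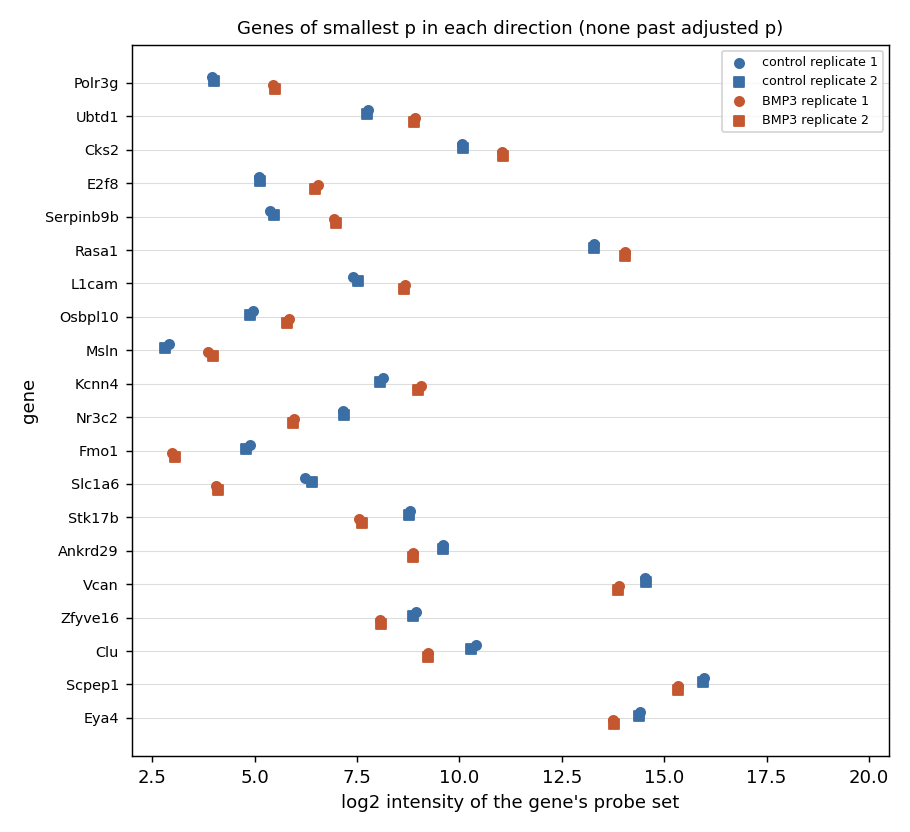
Log2 intensity of the 20 genes with the smallest unadjusted limma p and a fold of at least 1.5, 10 in each direction, with 1 point per array (circles, replicate 1; squares, replicate 2; blue, control; orange, BMP3). Selection by smallest p favours genes whose 2 arrays of a group lie close together, so that closeness is no separate finding. Cks2, for example, lies at 10.07 in control and 11.05 in BMP3 arrays, and no gene passed the adjusted threshold.

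Direct targets of BMP signalling through SMAD1/5 had lower values in BMP3 arrays for several members, but the list was not shifted as a group. Id2, an inhibitor of basic helix-loop-helix transcription factors, averaged 12.69 ± 0.17 in control and 11.01 ± 0.04 in BMP3 arrays, a log2 difference of -1.69 (SE 0.10, limma adjusted p = 0.213). Id2 was the only one of 22 measured members past 0.05 when adjusted over the list alone (adjusted p = 0.00793), against 0 adjusted over all probe sets. Its relatives Id3 and Id1 had differences of -0.81 ± 0.14 and -0.65 ± 0.24. Smad6, which encodes an inhibitory SMAD, had -0.44 ± 0.16. Of the 22 members, 8 were higher and 14 lower, with a median of -0.04 and a camera adjusted p of 0.239. The median was -0.08 without BMP3 replicate 1, -0.02 without control replicate 2 and 0.00 without BMP3 replicate 2. The 13 members averaging a log2 value of 6 or more had a median of -0.22. Targets of TGF-beta and activin through SMAD2/3 had 16 members higher and 10 lower (median 0.15, camera adjusted p = 0.456). That median was 0.03 without control replicate 1, 0.27 without control replicate 2, 0.35 without BMP3 replicate 1 and -0.04 without BMP3 replicate 2. In that list Bhlhe40 (0.58 ± 0.05) and Dact1 (-1.54 ± 0.20) were past 0.05 adjusted over the list alone, and 0 members were so adjusted over all probe sets. Smad7 had -0.47 ± 0.19 (its other probe set -0.02), Skil 0.44 ± 0.90 and Pmepa1 -0.14 ± 0.70. The level of this list followed the replicate number more than the treatment, at -0.36 and 0.19 in control replicates 1 and 2 and at -0.22 and 0.40 in BMP3 replicates 1 and 2. Skil and Pmepa1 turned direction when single arrays were left out, with ranges of -0.45 to 1.33 and of -0.92 to 0.64. Runx2 was not analysed here.

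**Figure D2:**
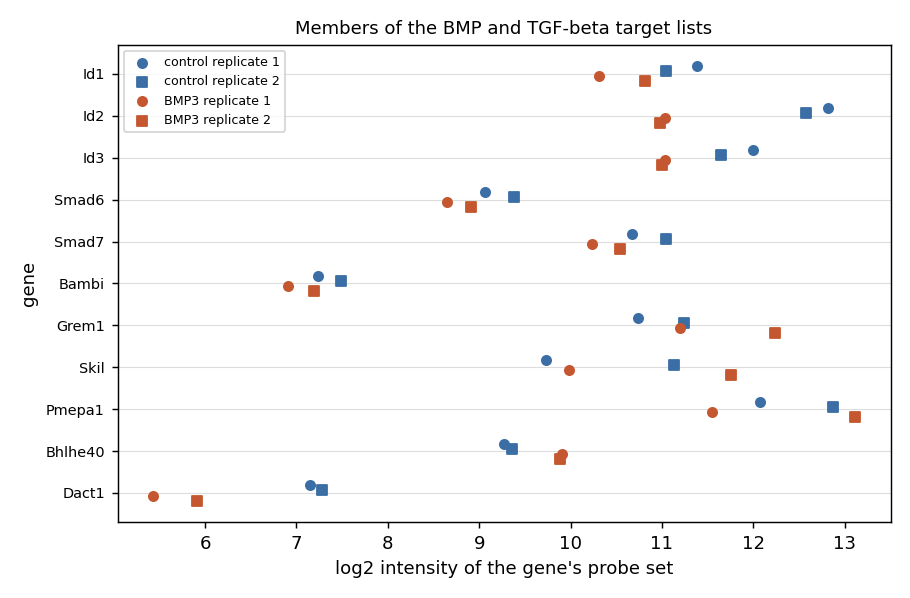
Log2 intensity on each array for 11 members of the BMP and the TGF-beta and activin target lists, picked for display after their values were seen (circles, replicate 1; squares, replicate 2; blue, control; orange, BMP3). Both BMP3 arrays lie below both control arrays for Id1, Id2 and Id3, whereas Skil and Pmepa1 separate by replicate number.

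Cell cycle and DNA replication genes were shifted higher in BMP3 arrays, with 25 of 29 measured members higher, 4 lower and a median log2 difference of 0.41 (camera adjusted p = 1.29e-05, and adjusted p = 0.906 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by the list's own adjustment, from 9.40 ± 0.05 to 10.69 ± 0.20 (difference 1.29, SE 0.12, adjusted p = 0.0395 when adjusted over the list alone). It was 1 member so called, and 0 were called adjusted over all probe sets. The mitotic kinase gene Cdk1 had a difference of 0.63 ± 0.10 and Ccnd1, which encodes cyclin D1, 0.53 ± 0.11. The list level was -0.19 and -0.34 in control arrays and 0.47 and 0.05 in BMP3 arrays. The median was 0.21 without BMP3 replicate 1 and 0.53 without BMP3 replicate 2. Among cyclin-dependent kinase inhibitors and p53 targets, which as a list were not shifted (camera adjusted p = 0.456), Cdkn2a had 0.72 ± 0.08 and Cdkn1b -0.72 ± 0.11.

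**Figure D3:**
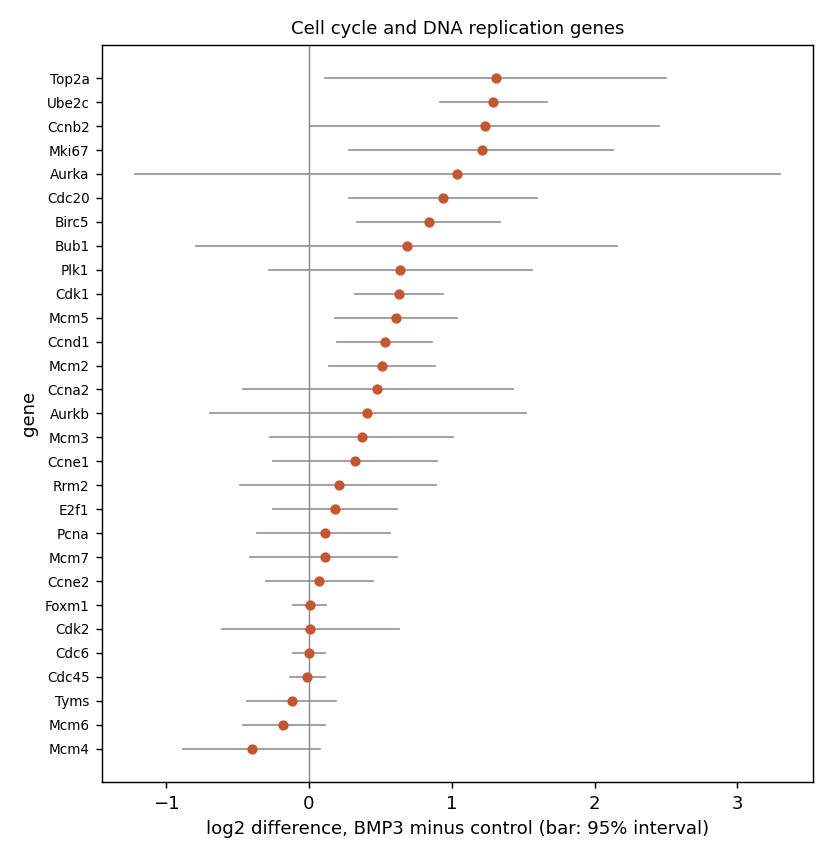
Log2 difference between BMP3 and control arrays for 29 cell cycle and DNA replication genes (points, limma estimate; bars, 95% confidence interval from 2 arrays per group; vertical line, no difference). Ube2c lies at 1.29 with an interval from 0.92 to 1.67, and 4 genes lie below 0.

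Genes of cholesterol synthesis, targets of the transcription factor SREBP2, were shifted higher, with all 16 measured members higher and a median of 0.82 (camera adjusted p = 9.47e-06, and adjusted p = 0.906 with an estimated correlation). Mvd, a mevalonate pathway enzyme, averaged 9.24 ± 0.53 in control and 10.29 ± 0.04 in BMP3 arrays, and Lss, which encodes lanosterol synthase, 10.66 ± 0.68 and 11.83 ± 0.12. Of the 16 members, 0 passed 0.05 adjusted over the list alone or over all probe sets. The list level was -0.88 in control replicate 1, 0.08 in control replicate 2, 0.24 in BMP3 replicate 1 and 0.56 in BMP3 replicate 2. The median was 0.35 without control replicate 1 and 1.27 without control replicate 2. The call was lost without BMP3 replicate 2, where the median was 0.61.

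Ribosome biogenesis genes had 18 of 20 members higher (median 0.32, camera adjusted p = 0.00581) and heat shock genes 13 of 14 (median 0.15, camera adjusted p = 0.0069). Adjusted p was 0.906 for both with an estimated correlation. Examples were Polr1b, a subunit of RNA polymerase I (0.29 ± 0.04), and the chaperone genes Hspa1a (0.63 ± 0.16) and Hspd1 (0.29 ± 0.08), while Ncl, which encodes nucleolin, had -0.18 ± 0.03, with its 4 probe sets averaging a log2 value of 6 or more running from -1.20 to 0.03. Neither call held under quantile normalization, median centring or cyclic loess, although the medians changed little. In that order they were 0.4, 0.36 and 0.32 for ribosome biogenesis and 0.13, 0.19 and 0.12 for heat shock genes. The ribosome biogenesis call was also lost without control replicate 1 (camera adjusted p = 0.105) and without BMP3 replicate 2 (0.88), and the heat shock call without control replicate 2 (0.0615) and without BMP3 replicate 2 (0.121). The ribosome biogenesis median was 0.07 without BMP3 replicate 2, 0.51 without control replicate 2 and 0.70 without BMP3 replicate 1. The heat shock median was 0.27 without BMP3 replicate 1.

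Interferon-stimulated genes were shifted lower, with 18 of 21 members lower and 3 higher (median -0.15, camera adjusted p = 0.00581, and adjusted p = 0.906 with an estimated correlation). Bst2, which encodes tetherin, averaged 9.81 ± 0.20 in control and 8.76 ± 0.06 in BMP3 arrays, and Usp18 4.02 ± 0.28 and 2.46 ± 0.36. The Usp18 level in BMP3 arrays lay below the median of each array. Only 10 of the 21 members averaged a log2 value of 6 or more, and these had a median of -0.40. Under quantile normalization the median of the whole list was -0.06 (camera adjusted p = 0.0467), and under median centring and cyclic loess it was -0.12. Hedgehog pathway genes had 8 of 11 members lower (median -0.10, camera adjusted p = 0.0376, and adjusted p = 0.906 with an estimated correlation). The 8 members of this list averaging a log2 value of 6 or more had a median of -0.45. The co-receptor gene Cdon had -0.64 ± 0.11 and the transcription factor gene Gli3 -0.53 ± 0.12. Adjusted over the list alone, 0 members of either list passed. Without BMP3 replicate 2 both calls were lost (camera adjusted p = 0.102 for each), and the Hedgehog call was lost without control replicate 1 as well (0.105). The interferon median was -0.04 without BMP3 replicate 2, -0.09 without control replicate 2 and -0.25 without BMP3 replicate 1. The Hedgehog median was -0.06 without BMP3 replicate 2, -0.18 without control replicate 1 and -0.16 without BMP3 replicate 1.

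**Figure D4:**
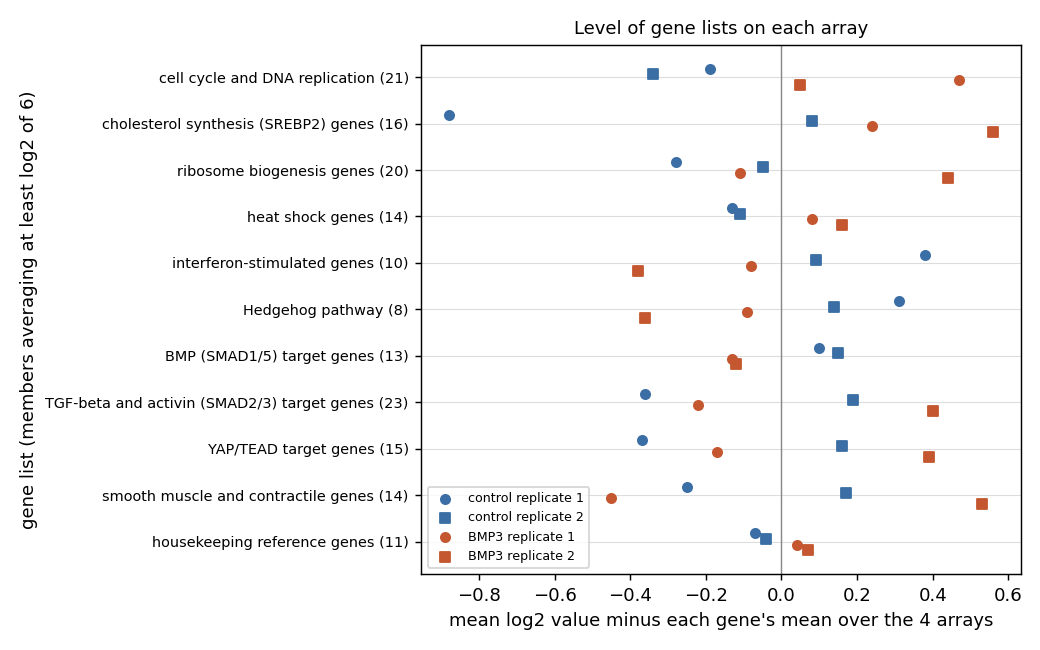
Level of 11 gene lists on each array, as the mean over members averaging at least a log2 value of 6 of the log2 value minus the gene's mean over the 4 arrays (number of such members in parentheses; circles, replicate 1; squares, replicate 2; blue, control; orange, BMP3). The cholesterol synthesis list is at -0.88 in control replicate 1 and between 0.08 and 0.56 on the other arrays, and the smooth muscle list runs from -0.45 to 0.53 within the BMP3 group.

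Lists were called along the replicate number as well. In the split of the 4 arrays into replicates 2 against replicates 1, 7 lists were called by the same test, among them cholesterol synthesis and ribosome biogenesis, and 701 probe sets passed the unadjusted p and the 1.5-fold threshold, against 6 lists and 1265 probe sets for BMP3 against control. The remaining split gave 29 probe sets and 2 lists, the unfolded protein response and ribosome biogenesis, so ribosome biogenesis was called in each of the 3 splits. Control probe sets differed along the treatment beside these gene groups. 18S ribosomal RNA stood at 11.41 and 10.50 in control and at 8.99 and 9.90 in BMP3 arrays. Each poly-A spike-in was lower in BMP3 arrays. Dap averaged 10.12 and 8.99, Phe 7.55 and 6.54, Lys 6.97 and 6.24, and Thr 5.91 and 5.43 in control and BMP3 arrays. The hybridization spike-ins averaged 11.59 and 11.55. In control replicates 1 and 2, Phe was 8.03 and 7.07, Lys 7.45 and 6.48, and Thr 6.22 and 5.59. For these spike-ins control replicate 2 lay nearer the BMP3 arrays than control replicate 1. Dap, at 10.39 and 9.86, did not follow this. Spike-ins are not transcripts of the cells, so their difference is not itself a change of a cell transcript. Whether it was related to BMP3 was not tested. The cause of the spike-in difference and its bearing on the gene lists were not tested either. The Gapdh 3' minus 5' log2 difference was -0.55 and -0.56 in control and -0.09 and -0.44 in BMP3 arrays, and that of beta-actin was 0.48 and 0.39 in control and 0.73 and 0.38 in BMP3 arrays.

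By limma's fry test for change in either direction, 6 lists passed an adjusted p of 0.05, with members going both ways, though in the endothelial list only Tek differed by much. They were hypoxia and glycolysis genes (adjusted p = 0.00496), extracellular matrix genes (0.0112), core clock genes (0.0112), BMP targets (0.0151), endothelial markers (0.0352) and ligands and antagonists of the superfamily (0.0441). In the split of replicates 2 against replicates 1 the same test called 8 lists, ligands and antagonists among them. The remaining split gave 0. With any 1 array left out, fry called 0 lists in either direction, and such a fit of 3 arrays has 1 residual degree of freedom, so these fits do not show whether a single array carried any of the 6 calls. In the matrix list, Vcan and Adamts5, an aggrecanase gene (-0.64 ± 0.07), were lower and Tnc, Timp1 and Fn1 higher adjusted over the list alone, the last 3 being named after their values were seen. The adjusted values over the list alone were 0.00545, 0.0327, 0.0369, 0.0372 and 0.039, and 0 members passed over all probe sets. Pkm, a glycolytic enzyme gene, had 0.67 ± 0.09 and Adm, which encodes adrenomedullin, -0.69 ± 0.13. In the ligand list, Tgfb2 had -0.98 ± 0.08 and Chrd 0.16 ± 0.04. Rgma, of the list of receptors and SMADs, which was not called, had 0.61 ± 0.14. In the endothelial list Tek, an angiopoietin receptor gene, averaged 8.63 ± 0.16 in control and 6.01 ± 0.33 in BMP3 arrays. Tek was the only member past 0.05 adjusted over the list alone (limma adjusted p = 0.00973), and each other member had 0.982. The next largest difference was that of Egfl7, at -0.18 ± 0.12. The list was not tested without Tek. Of the 12 endothelial members, 2 averaged a log2 value of 6 or more.

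Single members of lists that were not shifted had an unadjusted p under 0.05, with none past the adjusted threshold. Sfrp2, a secreted Wnt antagonist, averaged 7.07 ± 0.64 in control and 2.26 ± 0.03 in BMP3 arrays (limma adjusted p = 0.222). The BMP3 level lay below the median of each array, so no fold is given. Sfrp1 had a difference of -1.06 ± 0.21 at its brightest probe set, and its 4 probe sets averaging a log2 value of 6 or more ran from -1.06 to -0.24. The immediate early gene Fos averaged 11.25 ± 0.02 and 9.63 ± 0.17 (difference -1.62, SE 0.10), and Dusp1, a phosphatase of MAP kinases, had -0.33 ± 0.04. Hgf, which encodes hepatocyte growth factor, had -1.59 ± 0.16, Igf2 -0.86 ± 0.15, the chemokine genes Cxcl5 -1.85 ± 0.23 and Cxcl1 -1.50 ± 0.45, and Notch3 -1.40 ± 0.32. Hes1 of the same Notch list had 0.92 ± 0.23. Nqo1 of the NRF2 list had 1.32 ± 0.33, Thy1 and Cd44 of the mesenchymal surface list 0.73 ± 0.10 and 0.64 ± 0.19, and Crim1 of the YAP/TEAD list -0.82 ± 0.13. The Wnt, immediate early, growth factor, inflammatory and Notch lists had camera adjusted p of 0.686, 0.646, 0.443, 0.812 and 0.658.

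Lineage lists were not shifted with all 4 arrays. Adjusted camera p was 0.921 for osteoblast, 0.456 for chondrocyte, 0.646 for adipocyte and 0.456 for smooth muscle markers. A log2 value of 6 was reached on average by 8 of 16 osteoblast, 7 of 22 adipocyte and 14 of 19 smooth muscle members. Of 20 chondrocyte members only Col11a1, Col2a1 and Sox9 reached it, so the chondrocyte and adipocyte lists were mostly dim. Smooth muscle markers were called higher without BMP3 replicate 1 (median 0.42, camera adjusted p = 0.00182) and had a median of -0.15 without BMP3 replicate 2. In the chondrocyte list Col2a1, the main collagen of cartilage, had a difference of 1.15 ± 0.23 and Col11a1 -1.23 ± 0.24. In the adipocyte list Cebpd, an adipogenic transcription factor gene, had -1.07 ± 0.24 and Scd1 0.75 ± 0.21, and in the smooth muscle list Mylk had -1.11 ± 0.18 and Tpm2 0.20 ± 0.08. Sox9 had -0.38 ± 0.34 and Pparg -0.34 ± 1.18, and both turned direction when 1 of the arrays was left out. Markers of other cell types were mostly dim, with 0 of 12 skeletal muscle, 1 of 12 epithelial, 1 of 15 macrophage and blood, and 2 of 11 neuronal and glial members averaging a log2 value of 6 or more. Their camera adjusted p was 0.524, 0.921, 0.646 and 0.533. Of the neuronal members, Map2 had -0.79 ± 0.08, while Tubb3, under a log2 value of 6 on all arrays, had 0.5 ± 0.11. Stmn2, named after its values were seen, had 0.26 ± 0.06. Among receptors, Acvr1b had -0.32 ± 0.33 and Acvr2b, a receptor that binds BMP3, averaged 3.13 and 2.91 in control and BMP3 arrays, below the median of each array. The housekeeping list, with 8 of 11 members higher, had a median of 0.06 (camera adjusted p = 0.239), which was 0.11 without control replicate 1, 0.10 without BMP3 replicate 1 and 0.03 without control replicate 2. Of the other lists that were not shifted, camera adjusted p was 0.191 for the unfolded protein response, 0.228 for NRF2 targets, 0.239 for hypoxia and glycolysis, 0.456 for YAP/TEAD targets, mesenchymal surface markers and endothelial markers, 0.646 for matrix and core clock genes, 0.661 for ligands and antagonists, and 0.812 for receptors and SMADs. The unfolded protein response list was called higher without control replicate 2 (median 0.39, camera adjusted p = 0.0295) and without BMP3 replicate 1 (median 0.49, camera adjusted p = 1.27e-04), and had a median of -0.11 without BMP3 replicate 2. NRF2 targets were called higher without control replicate 1 (median 0.22, camera adjusted p = 0.0258) and had a median of -0.23 without control replicate 2. The YAP/TEAD median was -0.10 without control replicate 1 and 0.40 without control replicate 2.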

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

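A mouse repeat-element control probe set on the array, AFFX-MURINE_b1_at, which entered no comparison, had higher values in both BMP3 arrays (13.87 and 13.99) than in both control arrays (13.71 and 13.60). The gap between the groups exceeded the range within either group, and the log2 difference was 0.27. It was picked out of 64 control probe sets by that gap, and the difference was not tested.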

How the results depend on the processing

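The count of probe sets past limma's adjusted p of 0.05 was 0 higher and 0 lower under every alternative run, including an adjusted p under 0.1. At an unadjusted p under 0.05 it was 3779. Of 1390 values of the 94 named genes under the alternatives, 1382 kept their direction and 0 passed the adjusted threshold. The looser counts of 364 higher and 901 lower became 171 and 418 with an ordinary linear model and 217 and 301 with 1 probe set per gene, which tests fewer probe sets. With single arrays left out they ranged from 329 (without control replicate 1) to 870 (without BMP3 replicate 1) higher and from 742 (without control replicate 1) to 1407 (without BMP3 replicate 1) lower. Without BMP3 replicate 2, 625 were higher. These fits leave 1 array in a group and assume that it varies like the others. For the replicate block, the same-numbered arrays' deviations from group means correlated at 0.45 (0.60 over probe sets averaging at least a log2 value of 6). The looser counts were 683 and 1481, 5 lists were shifted higher with the unfolded protein response added (camera adjusted p = 0.0378), the cholesterol synthesis median stayed 0.82 (camera adjusted p = 2.77e-09), and the either-direction calls of BMP targets (0.0735), core clock (0.0877) and endothelial markers (0.0909) were lost. With 2 pairs this does not establish pairing.

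The number of lists shifted was 4 higher and 2 lower. It was 0 and 0 with an estimated correlation and with fry. It was 2 higher under quantile normalization, median centring and cyclic loess, and 1 lower with the mean of all probe sets of a gene. With arrays left out it ranged from 1 (without BMP3 replicate 2) to 6 (without BMP3 replicate 1) higher and from 0 (without BMP3 replicate 2) to 2 lower, with 1 lower without control replicate 1. Adjusted p was 0.906 for each of the 6 lists with an estimated correlation. With fry it was 0.543 for cell cycle, interferon and heat shock genes, 0.547 for Hedgehog, 0.699 for cholesterol synthesis and 0.873 for ribosome biogenesis genes. Heat shock genes had 0.166, 0.0677 and 0.347, and ribosome biogenesis genes 0.161, 0.179 and 0.0905, under quantile normalization, median centring and cyclic loess. Their medians there ran from 0.12 to 0.19 for heat shock and from 0.32 to 0.4 for ribosome biogenesis genes, against 0.15 and 0.32 as deposited. Heat shock genes also had 0.0567 without the dimmer probe sets by rank and 0.0677 without those under a log2 value of 6. Hedgehog genes had 0.0776 with the mean of all probe sets. Left-out arrays gave ranges of 0.0295 to 0.105 for Hedgehog, 0.00233 to 0.102 for interferon, 0.00166 to 0.121 for heat shock, 2.14e-15 to 0.0646 for cholesterol synthesis and 3.87e-08 to 0.88 for ribosome biogenesis genes. For cell cycle genes the median ran from 0.21 (without BMP3 replicate 1) to 0.53 (without BMP3 replicate 2). Of 15 alternatives, 13 kept the cell cycle call, all at the preset correlation, so they do not test that setting. The 2 without it, the estimated correlation and fry, lost the call. The fit on 1 probe set per gene repeated the main list test, which already used 1 probe set per gene.

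The number of lists called in either direction by fry, 6, was 10 with median centring, 3 without probe sets under a log2 value of 6, and 0 with any array left out. The ranges there were 0.136 to 0.313 for BMP targets, 0.122 to 0.996 for ligands and antagonists, 0.0972 to 0.997 for matrix genes, 0.122 to 0.253 for hypoxia and glycolysis, 0.124 to 0.232 for core clock and 0.136 to 0.232 for endothelial markers. Ligands and antagonists had 0.0598 with quantile normalization, 0.125 without the dimmer probe sets by rank, 0.17 without those under a log2 value of 6 and 0.47 with the mean of all probe sets. Hypoxia and glycolysis genes had 0.081 with quantile normalization, 0.1 with cyclic loess and 0.464 with the offset of 16. Core clock genes had 0.0598 with quantile normalization, 0.125 by rank and 0.212 under the log2 filter, where matrix genes had 0.0637. These alternatives for the either-direction calls were added after the calls were seen. Among named genes 5 turned direction in some fit without 1 array, with log2 differences of -0.45 to 1.33 for Skil, -0.92 to 0.64 for Pmepa1, -1.68 to 1 for Pparg, -0.79 to 0.02 for Sox9 and -0.64 to 0 for Acvr1b. Beyond the fewer arrays or probe sets in a fit, the cause was not tested.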

Other observations

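The tests on left-out arrays for the cell cycle, interferon and cholesterol lists were chosen after the values per array had been seen. The other tests here were written after the main list results and leading genes had been seen, but before their own values. The 6 further gene lists were picked after the leading genes were known, with those genes left out, and the rule by which they were read was altered after their values were seen, which moved 2 of them, the interleukin-6 and adventitial lists, from counting against a lower shift to undecided.

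Further gene groups that the comparison above does not cover were measured. Mitosis genes outside the fixed cell cycle list had 32 of 36 members higher in BMP3 arrays, with a median log2 difference of 0.37 (14 of the 36 averaged a log2 value of 6 or more), and S-phase genes outside it 26 of 35 with a median of 0.12. Fatty acid synthesis genes, targets of SREBP1, had 12 of 18 members higher with a median of 0.26. Complement genes, with 9 members measured, interleukin-6 receptor and STAT3 pathway genes, with 20, and adventitial fibroblast genes, with 21, had medians of 0.00, 0.02 and 0.00. Adjusted over all probe sets, 0 members passed in any of these 6 lists. Adjusted over the list alone, 1 passed in the S-phase list, 3 in the fatty acid list, 1 in the adventitial list and 0 in the other 3.

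The higher values of cell cycle genes were weighed first. A normalization that depends on brightness is argued against, since the list's median lay at percentile 100 of 10000 random lists matched on mean log2 value. Whether 1 array alone decides the call was left undecided. The highest camera adjusted p over the 4 fits without 1 array was 0.00398. Each of these fits leaves 1 array in a group and used the preset correlation, so passing there does not settle the question. The median was lowest without BMP3 replicate 1, at 0.21, against 0.41 with all 4 arrays. Its direction thus held in each fit, while its size depended in part on BMP3 replicate 1. Mitosis genes outside the list (camera adjusted p = 9.25e-07) and S-phase genes (0.0056) were shifted higher too, as a wider pattern would have it. They were read on the same 4 arrays, and the mitosis genes varied together (estimated correlation 0.81), so they are no separate support. The mitosis median was 0.06 without BMP3 replicate 1 and 0.71 without BMP3 replicate 2. The S-phase median was 0.07 without BMP3 replicate 1, the S-phase adjusted p was 0.101 without control replicate 2 and 0.0871 without BMP3 replicate 1, and with an estimated correlation the adjusted p were 0.753 and 0.666. A difference in growth state between cultures, apart from BMP3, was not tested and stays open.

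For the higher values of cholesterol synthesis genes, the list's median also lay at percentile 100 of matched lists, which argues against a brightness-dependent normalization. A low control replicate 1 may account for part of the size, since the median was 0.35 without that array against 0.82 with it. Fatty acid synthesis genes were higher as well (camera adjusted p = 0.00283, and adjusted p = 0.666 with an estimated correlation), but not past the threshold without BMP3 replicate 1 (0.0871). Their median was 0.13 without control replicate 1, 0.21 without control replicate 2, 0.18 without BMP3 replicate 1 and 0.37 without BMP3 replicate 2. The list level differed by 0.96 between the 2 control arrays and by 0.33 between the 2 BMP3 arrays, against 0.8 between the groups. The list was also called in the split of replicates 2 against replicates 1. Untreated cultures thus differed by more than the groups did. Whether such a difference between cultures, apart from BMP3, made the shift was not tested and stays open.

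For the lower values of interferon-stimulated genes, the median lay at percentile 0.02 of matched lists, which argues against a brightness-dependent normalization as the whole cause. Under quantile normalization the median was -0.06, against -0.15 with the values as deposited, and the camera adjusted p 0.0467. Under median centring and under cyclic loess the median was -0.12, so how much of the size remained depended on the normalization chosen. That 1 array decides the call is consistent with the highest camera adjusted p over the 4 fits without 1 array, which was 0.102 without BMP3 replicate 2, where the median was -0.04. An effect of BMP3 was not separated from that.

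For the other called lists, the median lay at percentile 100 of matched lists for ribosome biogenesis and at 2.19 for Hedgehog genes. The heat shock median of 0.15 lay at percentile 94.8, inside the range of -0.14 to 0.17 that held 95% of matched lists.

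Of the further lists, 3 were tested for lower values. Complement genes (camera adjusted p = 0.924), interleukin-6 receptor and STAT3 pathway genes (0.437) and adventitial fibroblast genes (0.924) were not shifted lower. The medians of the interleukin-6 and adventitial lists met the bound written beforehand against a lower shift, at 0 or above, but not by more than the spread of the members. The complement median, 0.00 after rounding, was slightly below that bound. Members of each list went both ways, so these tests leave that undecided.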
